A study of Mus musculus with 48 samples.

How the data were processed

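The values in all 6 deposited tables are normalised signal values that the authors made by dividing each library's gene read counts by 1 size factor. Per the submitters' processing notes, reads were checked with FastQC 0.11.7 and MultiQC 1.11, aligned to mm10 with STAR 2.5.0a, and normalised with DESeq2 1.30.1. Libraries were made, per the labels, from 10 ng of total RNA. The 18 neuron libraries share 1 table and 1 normalization, and each of the other tables was normalised separately, so levels are compared within a table unless RPM values are given. The read counts were recovered by dividing each library's values by its smallest step. All values (100%) then lay within 0.05 of a whole number, and size factors computed anew from the recovered reads equalled those of the deposited values, with a ratio of 1. The design had assumed counts, and the test planned for normalised signal was used instead. All 24421 gene entries were read, of which 27 have names turned into dates. Intervals and floors cover counting error only, since reads are not independent molecules.

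Each of the 8 comparisons was fitted with limma 3.58.1 in R 4.3.3, on log2(value + 1) with a mean-variance trend, 2 groups at a time and no block. Genes with a value of at least 10 in at least 3 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. On this scale a pseudocount shrinks the fold changes of genes that are low in every library, and a gene at 0 in part of a group can get a larger log2 difference than in edgeR, as Ddx3y did in hippocampal astrocytes (6.59 against 1.655). edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads, an addition chosen after the data were seen. Differences between effects were fitted by limma over 18 astrocyte, 18 neuron or 12 olfactory bulb libraries together, with recovered reads divided by size factors of the joint libraries. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and needed at least 3 tested members. There were 42 lists, 25 of biology and 17 of markers, and 6 more were added after the values were seen. Gene positions come from GENCODE vM21, release 21 for mouse.

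Genes were named by a rule fixed, like the design, the lists and most alternative settings, before the data were examined. The rule names 12 genes wherever they were tested, among them Slc22a3, Slc22a2, Slc29a4, Sox9, Maoa, Maob, Gad1, Tgm2, Fos, Npas4 and Arc. It then names up to 10 rising and 10 falling genes with the largest log2 change among those past an adjusted p of 0.05 whose groups do not overlap and whose higher mean reaches the median of tested genes, leaving out gene models. Where fewer than 3 genes passed, it names the 5 rising and 5 falling genes with the smallest unadjusted p. It adds up to 4 members of each list described, by the smallest unadjusted p.

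A self-test put changes into 200 genes of simulated libraries with the depth and spread of each comparison, 100 at 2-fold and 100 at 4-fold. limma recovered 23.2% of tested genes changed 2-fold and 54.1% of those changed 4-fold in olfactory bulb astrocytes, 0% and 3.16% in cortical astrocytes and 1.04% and 9.47% in hippocampal astrocytes. The shares were 2.02% and 40.9% in olfactory bulb neurons, 3.03% and 20.65% in cortical neurons and 1.02% and 21.98% in hippocampal neurons. They were 12.1% and 54.1% for CNO control against untreated and 3.06% and 30.9% for the libraries labelled Slc22a3-cKO. For differences of effects they were 0% and 6% between olfactory bulb and cortex in astrocytes, 0% and 6% in neurons, and 4% and 36% between Gq-CNO and CNO control. False calls by limma numbered at most 4, of 80 in olfactory bulb astrocytes, whereas DESeq2 made 36 false calls of 135 there, 44 of 58 in cortical astrocytes, 84 of 112 in hippocampal astrocytes and 48 of 99 for the libraries labelled Slc22a3-cKO.

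Nothing in the labels tells that libraries came from separate animals, so p-values measure the spread between these libraries. The labels give no pairing of replicate numbers, so none was used. Of the cortical and hippocampal astrocyte groups, 4 have a column numbered 4 that the labels assign to a group only. No library and no sample column was left out. Between libraries of a group, 48 pairs had a chi-square of at least 9.56 per gene, and 0 pairs were identical. The ribosomal RNA entry Rn45s, which took 7.997% to 23.05% of reads, was kept. Without molecular identifiers, PCR copies were not removed.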

Results

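Gene transcripts were measured by RNA sequencing in 48 libraries of sorted mouse brain cells, in 16 groups of 3. In 12 groups the mice carried a green fluorescent protein (GFP) under the promoter of Aldh1l1, a folate enzyme of astrocytes, and the labels name them Gq-CNO or Gq-Saline. Gq stands for a designer receptor that couples to Gq proteins, and clozapine-N-oxide (CNO) is its ligand. The sample titles do not say which cells carry the receptor. GFP astrocytes and cells labelled as mCherry (mCh) neurons were sorted from cortex, hippocampus and olfactory bulb of these mice. Another pair of groups held GFP astrocytes from the olfactory bulb of mice labelled CNO control or untreated. In the last pair, mCh astrocytes were sorted from the olfactory bulb of mice with floxed Slc22a3, labelled either with Gfap-Cre (Slc22a3-cKO) or with Gfap-mCh (flox control). The titles give mCh for both groups, while the column names give mCh for the flox controls and RFP for the cKO-labelled libraries.

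Depth is given as reads assigned to genes, divided by 1000000, in replicate order. Olfactory bulb astrocytes had 11.09, 11.03 and 3.08 with saline and 14.9, 12.8 and 4.23 with CNO. Cortical astrocytes had 8.60, 8.73 and 2.94 with saline and 5.54, 16.4 and 0.325 with CNO, and hippocampal astrocytes had 10.0, 18.3 and 11.6 with saline and 24.7, 12.3 and 2.11 with CNO. In these 4 groups the last library is numbered 4 in the tables. The neuron sorts had 1.75, 5.88 and 1.92 (saline) and 5.33, 5.19 and 3.67 (CNO) in the olfactory bulb. In the cortex they had 0.695, 1.26 and 2.49 (saline) and 2.45, 1.37 and 0.228 (CNO), and in the hippocampus 3.06, 6.80 and 2.23 (saline) and 2.63, 10.3 and 4.38 (CNO). CNO control libraries had 6.62, 8.58 and 7.15, untreated libraries 2.37, 1.73 and 2.96, flox control libraries 9.69, 12.5 and 8.91, and the libraries labelled Slc22a3-cKO 8.47, 13.4 and 7.496.

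The GFP astrocyte sorts were led by astrocyte transcripts, and the mCh sorts by microglial ones. In the 24 GFP libraries, the median over 16 astrocyte markers was 620.4 RPM (a gene's reads per 1000000 reads of its library, range over libraries 472 to 721), against 18 for 11 neuron markers and 8.13 for 12 microglia markers. Slc1a2, the main glial glutamate transporter, had a median of 50870 RPM there. In the 18 libraries of the neuron sorts, microglia markers stood at 772 (342 to 1237), oligodendrocyte markers at 203.5, neuron markers at 109 (51.2 to 214) and astrocyte markers at 99.7. Csf1r, the growth factor receptor of microglia, had a median of 2471 RPM in these sorts, and the myelin gene Mbp had 23730, against 851.5 for the synaptic gene Snap25. In the mCh astrocyte sorts from the olfactory bulb, microglia markers stood at 528 (flox control) and 814 (libraries labelled Slc22a3-cKO), and astrocyte markers at 66.9 and 52.4. The immediate early gene Egr1 had a median of 3235 RPM in the flox controls and 43.6 in the GFP sorts. The nuclear RNA Malat1 took 1.65% to 5.73% of the reads in the 9 CNO control, flox control and cKO-labelled libraries and 0.0544% to 1.025% in the other 39.

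**Figure D1:**
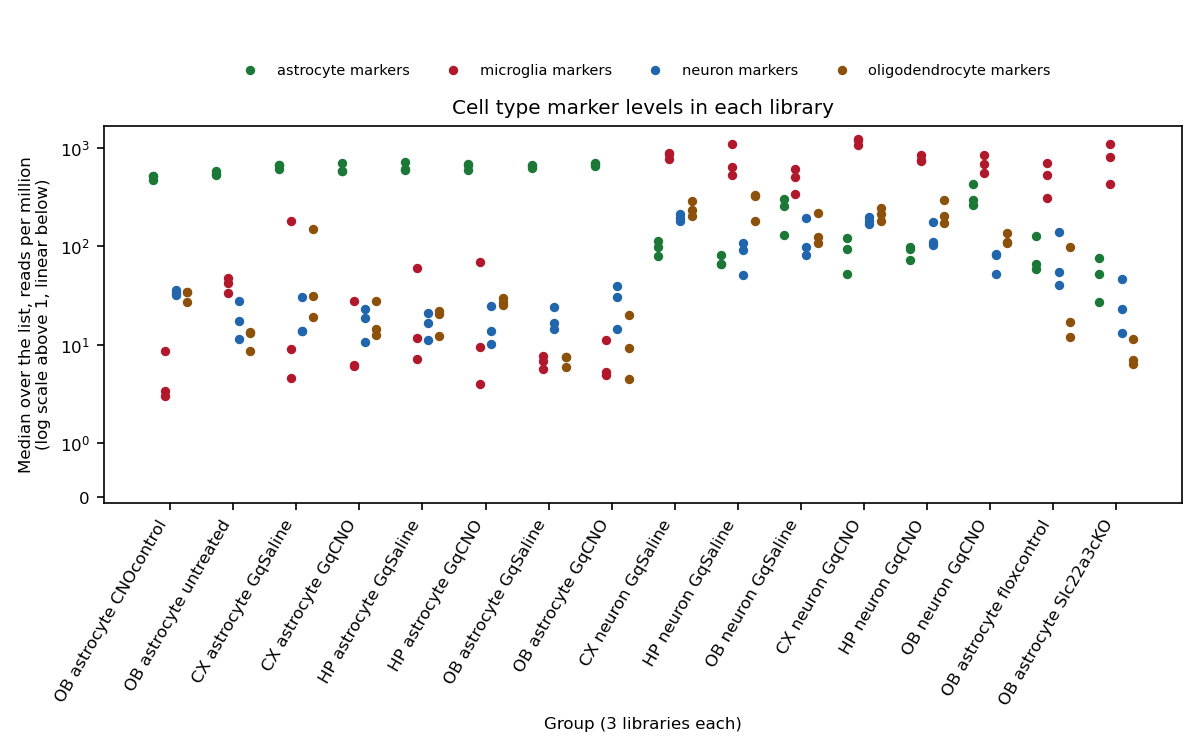
Median level over the astrocyte, microglia, neuron and oligodendrocyte marker lists in each library, in RPM on a log scale above 1, with 1 point per library and 3 libraries per group. Astrocyte markers lie between 472 and 721 in the GFP sorts, and microglia markers between 342 and 1237 in the neuron sorts.

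In olfactory bulb astrocytes, the comparison of Gq-CNO with Gq-Saline asks which transcripts differ when mice with the Gq label receive CNO. Spry2, which encodes a feedback inhibitor of receptor tyrosine kinase signalling, rose by 1.78 on the log2 scale (SE 0.302, adjusted p = 0.0354), from 288 ± 20.45 to 1063 ± 502 normalised reads (SD, n = 3 each). The gene (ENSMUSG00000022114.5) lies on chromosome 14 between 105891947 and 105896819 of mm10. The 3 Gq-CNO libraries had 895, 667 and 1627 normalised reads of Spry2, and the 3 Gq-Saline libraries 281, 311 and 272. Sox9, a transcription factor of astrocytes, stood at 2395 ± 377 against 2118 ± 384 (log2 difference 0.18, SE 0.18), and the other 7 tested genes of the always-named set lay between -1.11 (the activity-regulated gene Arc) and 0.54 (Npas4, -0.62 in edgeR), all with an adjusted p of at least 0.996. Of the genes with the smallest unadjusted p, the peroxisome assembly gene Pex3 (2.07) and the small leucine-rich proteoglycan gene Ogn (1.41) were higher, and the histone deacetylase gene Hdac9 (-1.25) and the nucleotide-sugar transporter gene Slc35a1 (-3.02) lower, and none of these passed.

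Slc22a3 encodes an organic cation transporter that carries monoamines, and the series centres on its astrocytic expression in the olfactory bulb. It lies on chromosome 17 between 12418960 and 12507704 (ENSMUSG00000023828.3). It was too low to be tested across genes. The Gq-CNO astrocytes of the olfactory bulb had 104, 0 and 4 reads of Slc22a3 (21.6 ± 31.1 normalised, SD, n = 3), and the 3 Gq-Saline libraries had 0. An exact two-sided permutation test gave p = 0.4, where 0.1 is the smallest that 3 against 3 allow. The olfactory bulb neuron sorts had 8, 2 and 21 reads with CNO (6.24 ± 7.04) and 0 in all 3 libraries with saline (exact permutation p = 0.1). Against the floor of 3 reads over the whole Gq-Saline group, Gq-CNO was at least 28.4-fold higher in the astrocyte and at least 6.95-fold higher in the neuron sort, which covers counting error only. Without the Gq-CNO library with most reads these bounds were 1.97-fold and 3.025-fold. Elsewhere, Slc22a3 had 14 reads in 1 hippocampal Gq-CNO astrocyte library, 32 in 1 hippocampal Gq-CNO neuron library and 0 in every cortical library. The neighbouring transporter gene Slc22a2 had 174 reads in the olfactory bulb Gq-CNO and 13 in the Gq-Saline astrocytes (39.7 ± 38.5 against 3.06 ± 2.83 normalised) and was not tested.

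**Figure D2:**
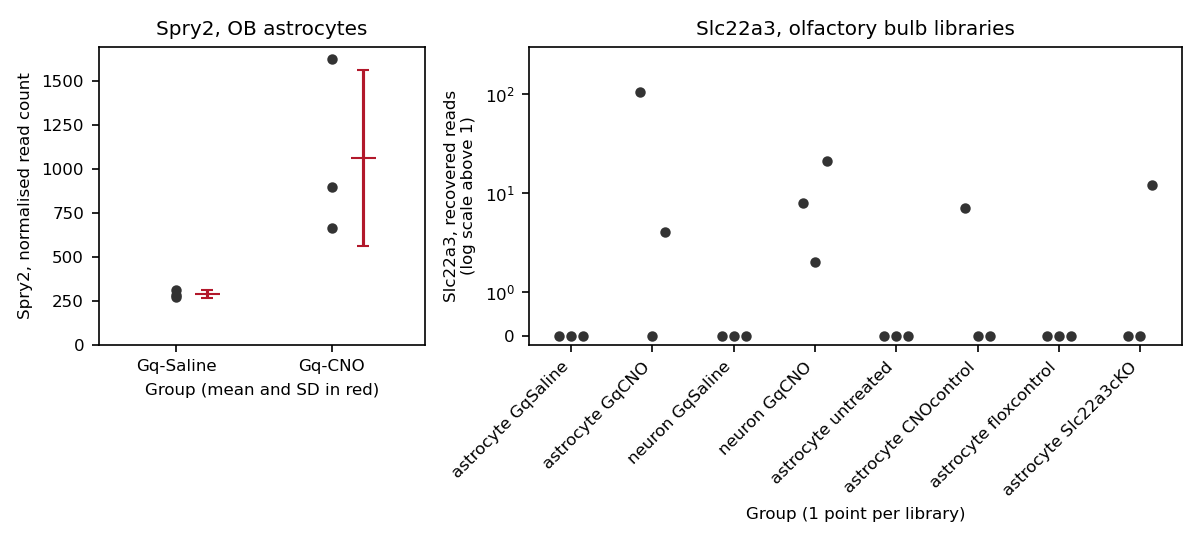
Left, Spry2 in normalised reads in olfactory bulb astrocytes, with 1 point per library and the mean and SD in red. Right, Slc22a3 reads per library in the 8 olfactory bulb groups on a log scale above 1, with 104 reads in the highest Gq-CNO astrocyte library and 0 in all Gq-Saline libraries.

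Across 11810 tested genes in olfactory bulb astrocytes, limma called Spry2 alone, with 564 genes at an unadjusted p under 0.05. edgeR also called it alone (adjusted p = 0.0432), and DESeq2 called 4 genes, namely Spry2, Onecut2, Slc35a1 and Zmym1, of which Onecut2 was named after its values were seen. The 2 groups did not overlap for 9.88% of genes, where chance gives 10%. Of 37 gene lists, the sex-linked genes alone passed (4 of 4 higher, median 2.51, camera adjusted p = 0.00172, 0 called over all genes and 1 adjusted over the list alone), with Ddx3y at 3.56 and Uty at 2.45, where edgeR gave 1.02 and 0.47 and a list median of 0.52. With an estimated correlation the adjusted p = 0.9635. Reads of the Y-linked Ddx3y were present in every Gq-CNO library, whereas Gq-Saline replicate 1 of each region and sort had Xist. The Spry2 call ended without Gq-CNO replicate 1 or 3, without saline replicate 1 or 3, and under quantile normalization (adjusted p = 0.0591), no trend (0.865), no low-value filter (0.2805) or a pseudocount of 0.1 (0.08596), and in 1 fit of all astrocyte groups, over a range of 2.88e-05 to 1 across all alternatives, while its log2 change stayed between 1.42 and 2.07. Without saline replicate 2, 2 genes passed, Spry2 and the prostaglandin D synthase gene Ptgds, the latter named after its values were seen.

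In cortical astrocytes no single gene passed, and camera called 3 gene lists, each with an adjusted p = 0.784 with an estimated correlation and with 0 members past the test, over all genes or adjusted over the list alone. The oligodendrocyte markers were lower in Gq-CNO in 8 of 8 measured members (median -1.09, camera adjusted p = 0.00297), with the myelin genes Mbp at -0.78 and Cnp at -0.70 and the lipid enzyme gene Ugt8a at -1.895. The immediate early genes, which neurons and glia switch on within minutes of stimulation, were lower in 9 of 11 (median -1.497, 0.0469), with Egr1 at -3.79, Jun at -3.20 (-1.67 in edgeR) and Arc at -1.497. Astrocyte markers were higher in 13 of 16 (median 0.24, 0.12 under quantile normalization, 0.0469), with the filament gene Gfap at 0.75, the glutamate transporter Slc1a2 at 0.38 and the glutamine synthetase gene Glul at 0.33. The saline library numbered 4 held 150.9 RPM of oligodendrocyte and 180.5 of microglia markers, against 31.6 and 18.9 (oligodendrocyte) and 4.59 and 8.995 (microglia) in the other saline libraries. It also carried the immediate early genes, with 2910 normalised reads of Egr1 against 26.01 and 19.18 in the other saline libraries, and 671 of Jun against 118 and 137.5.

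Single genes of cortical astrocytes with the smallest unadjusted p were the carboxypeptidase gene Cpd (-2.32), the growth factor signalling inhibitor Lrig1 (-1.91) and the anchoring protein gene Akap13 (-2.13) on the lower side and the ubiquitin ligase gene Arih1 (1.41) and the RNA export receptor Nxf1 (1.64) on the higher side. All had adjusted p = 0.9096. Sox9 stood at 1834 ± 55.4 against 1055 ± 747 normalised reads (SD, n = 3; log2 difference 1.28, 0.79 in edgeR), and the 6 tested always-named genes ranged from -2.12 to 1.28. limma called 0 of 9978 genes (142 at an unadjusted p under 0.05), edgeR 0 and DESeq2 16, and the groups did not overlap for 8.89% of genes, where chance gives 10%. Without both libraries numbered 4, an alternative chosen after the data were seen, 1 of the 36 lists passed, the sex-linked genes, and none of the 3 above.

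Hippocampal astrocytes showed no gene that passed. Pcdhac2, a clustered protocadherin of the cell surface, had 129 ± 122 normalised reads in Gq-CNO and 0 in Gq-Saline (SD, n = 3), the adaptor gene Cd2ap was at 1.585 and the tyrosine phosphatase gene Ptpn13 at -1.64, each with adjusted p = 0.976. Sox9 stood at 4143 ± 1460 against 4967 ± 298 (log2 difference -0.33), and the 7 tested always-named genes ranged from -0.33 to 1.28. Of 38 lists, the sex-linked genes passed (5 tested, median 4.67, camera adjusted p = 0.00274, 0 over all genes and 2 adjusted over the list alone), with Ddx3y at 6.59, Uty at 5.71 and Eif2s3y at 4.67, where edgeR gave 1.655, 1.80 and 1.35 and a list median of 1.35. With an estimated correlation the adjusted p = 0.872. limma called 0 of 11519 genes (234 at an unadjusted p under 0.05), edgeR 0 and DESeq2 19, with 8.855% of genes not overlapping where chance gives 10%.

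Whether the Gq-CNO effect in astrocytes differed between the 3 regions was tested as the difference between the regions' effects, over 12921 genes. No gene passed in limma or edgeR. At an unadjusted p under 0.05, limma gave 326 genes for olfactory bulb minus cortex, 187 for olfactory bulb minus hippocampus and 715 for cortex minus hippocampus, edgeR gave 633, 468 and 967, and DESeq2 called 19, 10 and 60. Across genes, which are not independent replicates, the log2 changes of the olfactory bulb and the cortex had Pearson's r = 0 and Spearman's rho = 0.01 over 9853 genes, those of the olfactory bulb and the hippocampus 0.03 and 0.03, and those of the cortex and the hippocampus 0 and -0.01.

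In the olfactory bulb neuron sort, camera called 7 of 36 gene lists, each with an adjusted p = 0.6904 with an estimated correlation and with 0 members past the test, over all genes or adjusted over the list alone. Astrocyte markers were higher in 15 of 16 (median 0.57, camera adjusted p = 7.29e-06), with the sodium pump subunit Atp1b2 at 0.74, Sox9 at 1.28 (0.81 in edgeR) and the glutamate transporter Slc1a3 at 0.58. Microglia markers were higher in 11 of 12 (median 0.27, 0.00787), with the fractalkine receptor Cx3cr1 at 0.81 and Tmem119 at 0.78. Neuron markers were lower in 10 of 11 (median -0.59, 0.00237), with the dendritic protein gene Map2 at -0.73 and the neurofilament gene Nefl at -0.90. Voltage-gated channels were lower in 14 of 19 (median -0.48, 0.00309), with Kcnq5 at -1.84, and synaptic genes in 19 of 24 (median -0.30, -0.48 in edgeR, 0.0274), with the kinase gene Camk2a at -0.71 and the NMDA receptor subunit Grin2b at -1.11. Astrocyte transcription factors (24 of 31 higher, median 0.28, 0.0484), with Id3 at 1.66, and astrocyte genes that regulate synapses (18 of 23 higher, median 0.39, 0.24 in edgeR, 0.0483), with Sparcl1 at 0.55, were the others.

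Saline replicate 1 of this sort held 195.5 RPM of neuron markers, against 98.7 and 81.9 in the other saline libraries and 52.5, 83.96 and 82.2 in Gq-CNO, and it held 131 of astrocyte markers against 306, 258.5, 295, 261 and 436. Single genes with the smallest unadjusted p, none of which passed (adjusted p = 0.9001), were the nucleotide-cleaving enzyme gene Entpd4 (-2.05), the neuronal calcium sensor Vsnl1 (-1.64), the death adaptor Fadd (4.74) and the zinc exporter Slc30a1 (2.14). The 9 tested always-named genes ranged from -0.81 (the monoamine transporter Slc29a4) to 1.28 (Sox9). limma called 0 of 10492 genes (556 at an unadjusted p under 0.05), edgeR 0 and DESeq2 5, namely P2rx3, Mamdc4, Tdp1, Zc4h2 and the gene model Gm5087, of which Zc4h2 falls under the naming rule and the others were named after their values were seen. The groups did not overlap for 10.6% of genes, where chance gives 10%.

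In the cortical neuron sort, interferon response genes were higher in Gq-CNO in 10 of 11 (median 1.17, camera adjusted p = 0.0387), with the antiviral sensor Ifih1 at 1.82, Ifit2 at 2.496 and the signal transducer Stat2 at 3.36. With an estimated correlation this list had an adjusted p = 0.887, and 0 members passed, over all genes or adjusted over the list alone. The adrenomedullin receptor gene Calcrl (-2.31), the axonal motor gene Kif5a (-0.70) and the G protein subunit gene Gng4 (2.59) were among those with the smallest unadjusted p and did not pass (adjusted p = 0.967). The 6 tested always-named genes ranged from -2.29 to 0.54. limma called 0 of 9392 genes (428 at an unadjusted p under 0.05), edgeR 0 and DESeq2 12, with 9.64% of genes not overlapping where chance gives 10%. Gq-CNO replicate 3 of this sort had 0.228 times 1000000 reads. With no low-value filter, limma called Hpca and Pon2, and in 1 fit of all neuron groups Znf512b, of which Hpca was named after its values were seen.

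In the hippocampal neuron sort, endothelial markers were lower in Gq-CNO in 7 of 7 measured members (median -1.87, camera adjusted p = 0.000587, 0 called over all genes and 3 adjusted over the list alone), with Ly6c1 at -5.125, the VEGF receptor Flt1 at -2.40 and the drug exporter Abcb1a at -2.08. Genes of potassium, water and gap junction transport were higher in 13 of 15 (median 0.30, 0.0234, 0 adjusted over the list alone), with the connexin gene Gjb6 at 1.29, and sex-linked genes in 4 of 4 (median 1.72, 0.33 in edgeR, 0.0234, 0 adjusted over the list alone). The 3 lists had an adjusted p = 0.408, 0.535 and 0.766 with an estimated correlation. Fam98a (-3.27, adjusted p = 0.433), the mitochondrial carrier gene Slc25a12 (-1.97) and the phosphatase gene Ppm1d (-2.61) were lower and the cholesterol synthesis gene Sqle (1.82) higher without passing. The transporter Slc29a4 stood at 5.79 ± 6.83 against 77.6 ± 95.5 normalised reads (SD, n = 3; log2 difference -3.18, adjusted p = 0.9896), and the 7 tested always-named genes ranged from -3.18 to 0.24. limma called 0 of 9808 genes (445 at an unadjusted p under 0.05), edgeR 0 and DESeq2 24, with 9.48% of genes not overlapping where chance gives 10%.

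The Gq-CNO effects of the neuron sorts were compared between regions over 12358 genes. limma called 0 for each pair of regions, with 633, 329 and 744 genes at an unadjusted p under 0.05 for olfactory bulb minus cortex, olfactory bulb minus hippocampus and cortex minus hippocampus. edgeR called 1, 0 and 0 genes and DESeq2 16, 0 and 26. The edgeR call was the zinc finger gene Znf512b (adjusted p = 0.0351), which limma called too when hippocampal saline replicate 1 was left out, and without cortical saline replicate 3 it called the fatty acid activating enzyme gene Acsbg1 for cortex minus hippocampus, named after its values were seen. Across genes, the changes of the 3 pairs of regions correlated with Pearson's r of 0.03 to 0.04. Of the activity genes, Fos was at -0.64 in the olfactory bulb and -0.06 in the hippocampal neuron sort, and was not tested in the cortical one. Arc was at 0.82, -0.94 and -0.05 in the olfactory bulb, cortical and hippocampal neuron sorts, and Npas4 at 0.49 in the olfactory bulb. None of these passed, so these genes do not show whether the receptor was activated.

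In olfactory bulb astrocytes of mice without the Gq label, the CNO control group was set against the untreated group, to ask what CNO does by itself. CNO cannot be told apart here from the library series. Nor can it be told apart from the handling that came with it, since no saline group without the Gq label was included. Column names of the CNO control libraries and of the floxed mice carry a DS number, and the untreated ones do not. Malat1 took 2.37% to 4.10% of the reads in CNO control and 0.25% to 0.43% in untreated libraries. Untreated replicate 3 also had 434 reads of Ddx3y, against 0 in each CNO control library. Immediate early genes were higher and microglial transcripts lower in the CNO control libraries. Fos, the classic activity-induced transcription factor (chromosome 12, 85473890 to 85477273), rose by 3.83 on the log2 scale (SE 0.378, adjusted p = 0.000148), from 73.7 ± 35.1 to 988 ± 267 normalised reads (SD, n = 3). Ctss, a lysosomal protease of microglia (chromosome 3, 95526786 to 95556403), fell by 4.40 (SE 0.505, adjusted p = 0.000298), from 371 ± 42.7 to 19.8 ± 13.4. S100b, a calcium-binding protein of astrocytes (chromosome 10, 76253853 to 76261159), fell by 1.89 (SE 0.149, adjusted p = 4.83e-05), from 2641 ± 230.2 to 714 ± 77.8. Hif3a, a hypoxia-inducible factor subunit (chromosome 7, 17031507 to 17062427), rose by 3.99 (SE 0.388, adjusted p = 0.000133), from 36.3 ± 13.1 to 595 ± 219.

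By group, 9 of 17 immediate early genes rose (11 adjusted over the list alone, median 2.62, camera adjusted p = 3.93e-07), among them Egr1 (2.76), the nuclear receptor Nr4a3 (3.23) and Jun (1.51). This list had an adjusted p = 0.327 with an estimated correlation. Of the microglia markers, 10 of 12 fell (11 adjusted over the list alone, median -3.34, camera adjusted p = 1.44e-10), with Csf1r at -2.77 and the complement genes C1qb at -3.955 and C1qc at -3.55, and 4 of 5 macrophage and leukocyte markers fell (4 adjusted over the list alone, median -2.86, 0.000935), with the mannose receptor Mrc1 at -4.10 and the hyaluronan receptor Lyve1 at -4.73. With an estimated correlation these had an adjusted p = 0.1803 and 0.449. Of glycolysis and lactate genes, 11 of 22 fell (14 adjusted over the list alone, median -0.64, camera adjusted p = 5.66e-07, 0.1803 as adjusted p with an estimated correlation), with the lactate dehydrogenase Ldhb at -1.25 and Gapdh at -1.001. Of cholesterol synthesis genes, 5 of 20 fell (7 adjusted over the list alone, median -0.43, 0.00148), with Hmgcs1 at -1.26 and the farnesyl diphosphate synthase Fdps at -2.38, and 2 of 10 endothelial markers fell (3 adjusted over the list alone, median -1.499, 0.0138), with the angiopoietin receptor Tek at -4.02. These had an adjusted p = 0.537 and 0.554 with an estimated correlation. Of the astrocyte markers, 7 fell and 1 rose of 16 (8 and 1 adjusted over the list alone, median -0.40, 0.0104, adjusted p = 0.554 with an estimated correlation), with Slc1a2 at -0.81, Gfap at -1.375 and Glul at -0.74. Under quantile normalization the median of this list was 0.007909, with 6 members down and 4 up.

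Beside these groups, the median over the microglia markers was 5.02 ± 3.18 RPM in the CNO control and 41.1 ± 7.40 in the untreated libraries (SD, n = 3), and that over astrocyte markers 505 ± 29.04 and 555 ± 28.3. Neuron markers stood at 33.6 ± 1.99 and 18.9 ± 8.31, oligodendrocyte markers at 31.8 ± 4.24 and 11.8 ± 2.68, and olfactory ensheathing markers at 57.25 ± 13.8 and 19.4 ± 1.72, none of which passed camera. For microglia markers, olfactory bulb Gq-CNO and Gq-Saline astrocytes held 4.96 to 11.05 RPM, so the untreated libraries stood apart. Malat1 rose by 3.04 (adjusted p = 1.25e-05), from 14730 ± 3616 to 120700 ± 28690 normalised reads, and 71 of 76 ribosomal protein genes fell (median -1.985, also 71 in edgeR). Both were picked out after their values were seen, and reads of ribosomal protein genes can be shared with their many processed copies. The largest rises by the naming rule included Coch (5.63), the matrix gene Ltbp2 (5.19), the X-inactivation RNA Xist (4.79) and the transcription factor gene Klf4 (4.23), and the largest falls among genes at or above the rule's level were those of Ctss and Mrc1. Sox9 was at 1908 ± 182 against 1505 ± 331 normalised reads (log2 difference 0.36, adjusted p = 0.202). Slc22a3 had 7, 0 and 0 reads with CNO and 0 in each untreated library.

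limma called 1332 of 10940 genes in this comparison (579 higher, 753 lower), edgeR 1353 and DESeq2 2072, with 1264 called by all 3. The groups did not overlap for 32.9% of genes, where chance gives 10%. Without CNO control replicate 1, 2 or 3 the count was 797, 551 or 526, and without the trend 395. The median log2 change of all genes was 0.107, and 0.006209 with edgeR's scaling. Xist was not called by edgeR (adjusted p = 0.196), Ltbp2 was lost without any 1 of the CNO control libraries or without the trend, Klf4 also without untreated replicate 3, without the filter, with a pseudocount of 0.1 or in DESeq2, and Ldhb, Fdps, Nr4a3, Egr1, Csf1r, C1qb, C1qc, Mrc1 and Lyve1 were lost under none of the alternatives that could test them. The labels give no dose or time for CNO.

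Whether the Gq-CNO effect differed from the CNO control effect in olfactory bulb astrocytes was tested over the 12 libraries together. The effects differed for 667 of 12554 genes (441 with a higher and 226 with a lower Gq-CNO effect, edgeR 744). Of these, 608 were also called between CNO control and untreated, and 1 between Gq-CNO and Gq-Saline. Spry2 had a Gq-CNO effect higher by 2.11 (SE 0.436, adjusted p = 0.00376). It was picked from the same Gq-CNO and Gq-Saline libraries, so this is no independent support for its call. Malat1 had a difference of -3.43, and 68 of the differing genes encode ribosomal proteins. The count was 433 without CNO control replicate 2, 396 without replicate 3 and 186 without the trend, and DESeq2 called 1132. Across 10637 genes the changes of the Gq-CNO and CNO control comparisons had Pearson's r = -0.04 and Spearman's rho = -0.05.

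The last comparison asks what changes in the olfactory bulb when Slc22a3 is deleted in Gfap-expressing cells. Slc22a3 itself had 0, 0 and 0 reads in the 3 flox control libraries, which allows up to 0.3097, 0.241 and 0.337 RPM, and 0, 0 and 12 reads in the 3 libraries labelled Slc22a3-cKO. The 12 reads come to 1.601 RPM, and the normalised means were 5.11 ± 8.85 and 0 (SD, n = 3). Fitted without the low-value filter, its log2 difference was 1.34 (adjusted p = 0.563). The targeted gene therefore does not check the labels, and the group is called the libraries labelled Slc22a3-cKO. Whether reads fall inside the floxed part is not given in the sources used here.

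In the libraries labelled Slc22a3-cKO, camera called 21 of 38 gene lists, and with an estimated correlation their adjusted p ran from 0.251 to 0.518. Interferon response genes were among those that rose (12 of 20), and 3 of 16 astrocyte, 4 of 11 neuron and 1 of 10 oligodendrocyte precursor markers fell. Cxcl9, an interferon-gamma-induced chemokine that draws T cells (chromosome 5, 92321347 to 92328079), rose by 8.74 on the log2 scale (SE 0.579, adjusted p = 5.52e-05), from 83.9 ± 72.0 to 31470 ± 15310 normalised reads (SD, n = 3). C3, the central complement component (chromosome 17, 57203970 to 57228136), rose by 6.54 (SE 0.588, adjusted p = 0.000243), from 80.0 ± 57.9 to 7644 ± 4440. Aqp4, the water channel of astrocyte endfeet (chromosome 18, 15389496 to 15410982), fell by 2.40 (SE 0.293, adjusted p = 0.00171), from 4677 ± 1331 to 864 ± 59.5.

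Of 20 interferon response genes, 12 rose (18 adjusted over the list alone, median 1.99, camera adjusted p = 4.97e-19), with Irf7 at 3.74 and the chemokine Cxcl10 at 3.485. Of the genes of the A1 reactive astrocyte state, 5 of 10 rose (6 adjusted over the list alone, median 2.25, 7.20e-08), with the guanylate-binding protein gene Gbp2 at 5.31, the immunity-related GTPase Iigp1 at 4.37 and the class I antigen gene H2-D1 at 2.55, and 3 of 8 of the pan-reactive genes rose (3 adjusted over the list alone, median 0.43, 0.27 under quantile normalization, 0.0143), with the hyaluronan receptor Cd44 at 2.498. Each of these had an adjusted p = 0.251 with an estimated correlation. In these libraries microglia markers stood at 814 RPM and astrocyte markers at 52.4. The lists therefore do not tell which cells the transcripts came from. Gbp2 and Iigp1 are also of the guanylate-binding protein and immunity-related GTPase families counted below, so these lists are not independent. Of cytokine and chemokine genes, 3 of 18 rose (10 adjusted over the list alone, median 1.204, 1.86e-07, adjusted p = 0.287 with an estimated correlation), with Il1b at 2.29 and Ccl5 at 6.32. In lists put together after the values were seen, 7 of 7 class II antigen presentation genes rose (median 5.20, with Cd74 at 5.46), 17 of 17 guanylate-binding protein and immunity-related GTPase genes (median 3.28) and 3 of 3 of the chemokines Cxcl9, Cxcl10 and Cxcl11 (median 6.13), with the same counts in edgeR. Of 20 immediate early genes, 3 rose (4 up and 1 down adjusted over the list alone, median 0.24, 0.0262, adjusted p = 0.518 with an estimated correlation), with Nr4a3 at 3.39, Egr3 at 2.00 and Egr2 at 1.44, and the list median was -0.02 under quantile normalization and 0.11 in edgeR.

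Microglia markers were higher without any member passing over all genes (0 of 12, 6 adjusted over the list alone, median 1.00, camera adjusted p = 0.000235, adjusted p = 0.476 with an estimated correlation), with Ctss at 1.88 and C1qa at 1.66. Of the astrocyte markers, 3 of 16 fell (6 adjusted over the list alone, median -0.96, 3.58e-06, adjusted p = 0.338 with an estimated correlation), with Slc1a2 at -2.16 and the growth factor receptor Fgfr3 at -3.84. Glutamate handling (5 of 15 fell, 9 adjusted over the list alone, median -2.13, 1.04e-06) had the receptor subunit Gria2 at -3.25 and the glutamine transporter Slc38a3 at -3.09, and GABA handling (3 of 19 fell, 9 down and 1 up adjusted over the list alone, median -1.41, 8.14e-05) had the GABA transporter Slc6a11 at -3.55. Each of these 2 lists had an adjusted p = 0.251 with an estimated correlation. Potassium, water and gap junction genes (1 of 17 fell, Aqp4; 5 adjusted over the list alone, median -0.78, 0.00218), astrocyte genes that regulate synapses (5 of 25 fell, 9 down and 1 up adjusted over the list alone, median -1.26, -0.79 in edgeR, 5.65e-05), with the proteoglycans Ncan at -2.36 and Bcan at -2.81, calcium signalling genes (3 of 28 fell, 7 adjusted over the list alone, median -0.56, 0.00111), with the calcium pump Atp2b4 at -2.63, and astrocyte transcription factors (1 of 31 fell, Rorb at -3.395; 3 down and 2 up adjusted over the list alone, median -0.43, 0.0186) passed too. With an estimated correlation these 4 had an adjusted p = 0.371, 0.287, 0.251 and 0.518.

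Synaptic genes (7 of 24 fell, 20 adjusted over the list alone, median -2.24, camera adjusted p = 2.84e-11) had Snap25 at -2.75 (2060 ± 1451 against 13170 ± 7272 normalised reads) and Syp at -2.59, neuron markers (4 of 11, 9 adjusted over the list alone, median -2.44, 1.295e-07) had the neurofilament gene Nefm at -3.34, and voltage-gated channels (3 of 19, 9 adjusted over the list alone, median -1.82, 1.86e-07) had the sodium channel Scn8a at -2.04. These had an adjusted p = 0.251, 0.276 and 0.251 with an estimated correlation. Glutamatergic neuron markers (1 of 8, 4 adjusted over the list alone, median -2.07, 0.00108), GABAergic neuron markers (0 of 7, 5 adjusted over the list alone, median -2.63, 0.000791) and neuroblast markers (1 of 6, Dcx at -4.02, 1 adjusted over the list alone, median -1.53, 0.0352) were lower, with an adjusted p = 0.251, 0.287 and 0.269 with an estimated correlation. Oligodendrocyte precursor markers (1 of 10, Gpr17 at -6.29, 5 adjusted over the list alone, median -2.935, 0.000234) and oligodendrocyte markers (0 of 10, 3 adjusted over the list alone, median -1.695, 0.00354) were lower as well, with an adjusted p = 0.251 and 0.448 with an estimated correlation. Enpp6, which newly formed oligodendrocytes express, was at 0 in all 3 libraries labelled Slc22a3-cKO (adjusted p = 0.0105).

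**Figure D3:**
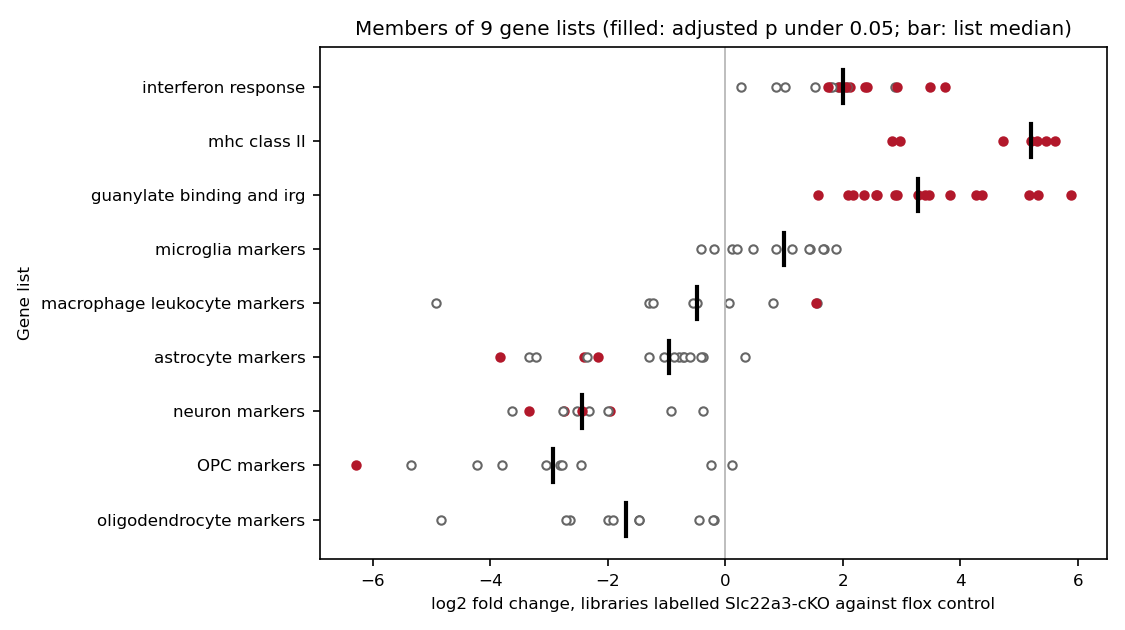
Log2 fold change of each member of 9 gene lists in the libraries labelled Slc22a3-cKO against flox control, with filled points for an adjusted p under 0.05 and a bar at the list median. The medians are 1.99 for interferon response genes, 1.00 for microglia markers and -2.44 for neuron markers.

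Further rises by the naming rule were the itaconate enzyme gene Irg1 (9.82, 1690 ± 740 against 1.37 ± 2.37 normalised reads), H2-M2 (9.52), the B cell chemokine Cxcl13 (8.24), Serpina3f (7.82) and the opioid precursor gene Pdyn (7.19), and further falls the ephrin receptor Epha4 (-5.385), Aplp1 (-5.31) and the matrix gene Tnr (-4.10). Tgm2, the transglutaminase known to attach monoamines to proteins, rose by 2.34 (SE 0.4203, adjusted p = 0.01595), from 234 ± 62.4 to 1236 ± 501.5. Sox9 stood at 305 ± 252 against 456 ± 171 (log2 difference -0.88, adjusted p = 0.4796), Fos at 0.71 (0.291), Npas4 at -5.09 (0.0522), Gad1 at -2.42 (0.0972) and the monoamine oxidase gene Maoa at -1.055 (0.292). All 76 ribosomal protein genes tested were higher (median 1.19), with 6 called by limma and 2 by edgeR.

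limma called 341 of 13465 genes (184 higher, 157 lower), edgeR 267 and DESeq2 1326, with 256 called by all 3. The groups did not overlap for 22.7% of genes, where chance gives 10%. The median log2 change of all genes was -0.10, and 0.006718 under quantile normalization. The count was 81 without cKO-labelled replicate 1 or 2, 1277 without replicate 3, and 149, 105 and 212 without flox control replicate 1, 2 or 3, 165 without the trend and 195 with a pseudocount of 0.1. Of 63 called genes picked by the naming rule, 12 were lost under no alternative that could test them, namely Cxcl9, Cxcl13, C3, Irg1, Iigp1, Gbp2, H2-M2, Nr4a3, Serpina3f, Cd300lf, Aqp4 and Tnr. Of the 38 lists, 21 passed (6 up, 15 down), 0 with an estimated correlation and 0 with fry, which tests whether a set's genes move, on balance, 1 way and does not compare them with other genes. In the CNO control comparison fry called 9 lists.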

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

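The tests of CNO itself, of library series, of cell shares, of the vector and of Slc22a3 reads were chosen only after the results were seen, as were the regroupings of the Gq-CNO and CNO control labels. The test of sequencing depth in the CNO control comparison was added after the data were seen but before its own result was, and the other splits of the libraries were planned.

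Between the Gq-CNO effect and the CNO control effect in olfactory bulb astrocytes, 667 genes differed, a difference between groups under a like contrast. Among them were Malat1 (difference -3.43) and Spry2 (2.11). Of 100 splits of the labels, 2 gave as many genes, the real one included, and the highest other gave 708. When the Gq labels alone were regrouped, the 19 other groupings gave 404 to 723 genes (median 537), 3 of them at least as many. With the CNO control and untreated labels alone regrouped, others gave 0 to 458 (median 0) and 0 gave as many. The differing genes thus follow the CNO control and untreated libraries rather than the Gq-CNO ones.

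The first pattern weighed is the set of genes that differ between CNO control and untreated, in which Fos, Egr1 and Hif3a rose and Ctss, Csf1r and S100b fell. CNO itself, as given to the Gq-CNO mice, is argued against, since the called genes had a median signed log2 change of -0.05438 there, against 1.321 in their own comparison, and 41.08% had the same sign. Sequencing depth is argued against, since 1374 genes were called after every library was thinned to the reads of the shallowest, 1217 of them the same genes. A candidate explanation is the library series. The called genes had a median of 1.595 between flox control and olfactory bulb Gq-Saline libraries, with 88.51% of the same sign. Malat1 stood at 4.08 there, but these groups also differ in sort and in mice. Microglial genes went the other way, with microglia markers at 311 to 709 RPM in flox control and 5.71 to 7.57 in Gq-Saline libraries. This contrast therefore gives the series no support for the falls of Ctss and Csf1r. The CNO given to the control mice, at a dose and time that the labels do not state, stays open, and so does the handling that came with it.

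The second pattern is the rise of interferon genes such as Irf7 and Cxcl10 in the libraries labelled Slc22a3-cKO. A larger share of microglia with unchanged expression, as the whole cause, is argued against, since the interferon list's median exceeded that of microglia markers by 0.9937 (permutation test over genes, p = 9e-05, 100000 resamples). The microglia markers ranged from -0.41 to 1.88, so a larger share of microglia in another state stays open. A larger share of macrophages and leukocytes as a whole is argued against as well, as the median of those markers was -0.49. The difference was 2.485 (p = 3e-05, permutation test). The 9 markers ranged from -4.92 to 1.56, so a larger share of 1 kind of leukocyte stays open. Both tests shuffle genes, which are not independent replicates, and do not measure the spread between libraries. The interferon list was weighed because it rose, so these p-values are no independent support. Activation of the microglia present, whose Csf1r stood at 1807 RPM, may contribute and was not tested. The vector rather than gene loss stays open, because 0 libraries had Cre and no floxed gene.

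The third pattern is Slc22a3, which had reads in 5 of 6 olfactory bulb Gq-CNO libraries and in 0 of 6 Gq-Saline libraries, where the sorts of a group may come from the same mice, and the exact permutation tests within a sort gave p = 0.4 and 0.1. Without the library with most reads, 5.92 reads would have been expected in the Gq-Saline astrocytes and 9.07 in the neurons, and 0 were found. These numbers take reads as independent molecules, so deeper sequencing of the Gq-CNO libraries stays open. So does 1 library with many copies of few molecules, as in the astrocytes only 1 other Gq-CNO library had reads, with 4. An effect of the receptor on Slc22a3 stays open too.

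For each 3 against 3 comparison, the 10 splits of the 6 libraries are too few for a share under 0.05. In olfactory bulb astrocytes, 2 splits gave as many genes as the real 1 (highest other 1), and 10 gave as many lists as the real 1 (highest other 10). In cortical astrocytes, 10 gave as many genes as the real 0 (highest other 0) and 5 as many lists as the real 3 (7). In hippocampal astrocytes these were 10 for 0 genes (0) and 8 for 1 list (7). In the neuron sorts they were 10 for 0 genes (1) and 9 for 7 lists (16) in the olfactory bulb, 10 for 0 genes (0) and 5 for 1 list (5) in the cortex, and 10 for 0 genes (1) and 6 for 3 lists (5) in the hippocampus. For CNO control against untreated, 1 split gave as many genes as the real 1332 (highest other 0) and 3 as many lists as the real 7 (10). For the libraries labelled Slc22a3-cKO, 1 gave as many genes as the real 341 (0) and 2 as many lists as the real 21 (22).

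For the differences of Gq-CNO effects between regions, 100 of 100 splits gave as many genes as the real 0 for each pair of regions. The highest other counts were 1, 0 and 5 in astrocytes and 0, 0 and 3 in neurons, for olfactory bulb minus cortex, olfactory bulb minus hippocampus and cortex minus hippocampus.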

How the results depend on the processing

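The edgeR and DESeq2 fits, thinning, leaving out both libraries numbered 4, the fit of all astrocyte groups, the quantile and no-trend alternatives of the joint fits and all region differences were chosen after seeing the data; the other alternatives were planned. The cause of each change below was not tested.

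In olfactory bulb astrocytes the call of Spry2 fell to 0 genes under quantile normalization, without the trend, with no filter, with a pseudocount of 0.1, with a replicate block and in 1 fit of all astrocyte groups. Leaving out a library gave 0 to 2 genes, with 0 without Gq-CNO replicate 1 or 3 or saline replicate 1 or 3 and 2 without saline replicate 2. No filter gave 2 genes in cortical neurons and 1 fit of all neuron groups gave 1 there, against 0. Leaving out a library gave 0 to 0 genes in the cortical and hippocampal astrocytes and in the 3 neuron sorts.

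DESeq2 gave 4 genes in olfactory bulb, 16 in cortical and 19 in hippocampal astrocytes, 5, 12 and 24 in the neurons of these regions, 2072 for CNO control and 1326 for the libraries labelled Slc22a3-cKO. Its simulated false calls are given with the processing.

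For CNO control against untreated, no trend gave 395 genes against 1332, and leaving out a library 526 to 1614, with 797, 551 and 526 without CNO control replicate 1, 2 and 3. Fos, Egr1, S100b, Hif3a and Ctss kept their calls under every alternative run. For the libraries labelled Slc22a3-cKO, no trend gave 165 genes, a pseudocount of 0.1 gave 195 and the replicate block 105, against 341. Leaving out a library gave 81 to 1277, with 81 without cKO replicate 1 or 2, 1277 without replicate 3, and 149, 105 and 212 without flox control replicate 1, 2 and 3. The log2 difference of Slc22a3 ranged from 0 to 2.015 when a library was left out.

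Gene lists called fell to 0 in all 8 comparisons with an estimated correlation. In cortical astrocytes, 1 list was called without both libraries numbered 4, against 3. With the replicate block, 3 lists were called in hippocampal astrocytes against 1, 0 in cortical neurons against 1 and 8 in hippocampal neurons against 3, and 12 genes were called in hippocampal astrocytes against 0. After centring, Pearson's r across genes between treatment groups' libraries of the same number ran from -0.16 to 0.13, and in 0 of 8 comparisons did every pair exceed 0.1. A hint of pairing came from the hippocampus, where 6 of 6 neuron and 4 of 4 numbered astrocyte libraries correlated best with their own number. Numbers across regions and sorts were not checked this way, and Xist in Gq-Saline replicate 1 of each region and sort leaves open that a number stands for 1 mouse there.

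For Gq-CNO effects between regions in astrocytes, no filter gave 1 gene for olfactory bulb minus cortex and 1 for cortex minus hippocampus, against 0, and DESeq2 19, 10 and 60, with 0 to 0 when a library was left out. In neurons, edgeR gave 1 and DESeq2 16 for olfactory bulb minus cortex, and DESeq2 26 for cortex minus hippocampus. Leaving out a library gave 0 to 1 (1 without hippocampal saline replicate 1), 0 to 0 and 0 to 1 (1 without cortical saline replicate 3). Between Gq-CNO and CNO control, no trend gave 186 and DESeq2 1132 genes against 667, and leaving out a library 396 to 716, with 433 and 396 without CNO control replicate 2 and 3.

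For the region differences of astrocytes, the replicate block gave 1299 genes for olfactory bulb minus cortex, 1085 for olfactory bulb minus hippocampus and 246 for cortex minus hippocampus, against 649, 472 and 19. DESeq2 gave 800 and 229 for the last 2, and quantile normalization 33 for the last. Leaving out a library gave 436 to 763, 347 to 769 (769 without cortical saline replicate 4) and 11 to 51. For cortex minus hippocampus the count was 48 and 51 without cortical saline replicate 1 and 4, 11 without cortical Gq-CNO replicate 4 and 12 without hippocampal saline replicate 4.

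Of the other values of these counts, 333 kept their side and size. For single named genes 4678 values kept their state, which includes genes not called in either fit, while 378 lost and 90 gained a call. Under quantile normalization 3 of the 1332 genes called for CNO control turned direction, and 2 of the 44 called lists had a median of the other sign, namely astrocyte markers for CNO control (0.007909) and immediate early genes in the libraries labelled Slc22a3-cKO (-0.02). Of the genes named by the rule, 20 of 43 called in the CNO control comparison, 12 of 63 in the libraries labelled Slc22a3-cKO and 0 of 1 in olfactory bulb astrocytes were lost under no alternative. The self-test recovered least in cortical astrocytes (3.16% of 4-fold changes), where saline library 4 correlated with the other saline libraries at a Spearman's rho of 0.54 and 0.559 across genes. Cortical neurons held the shallowest library, with 0.228 times 1000000 reads, and there it recovered 20.65%. Depth limits what 0 reads of Slc22a3 show, which in the flox controls together allow up to 0.0966 RPM.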

Other observations

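Tests of the region differences and of ERK feedback were chosen only after the results were seen. The GFP astrocyte sorts of the 3 regions were compared over Gq-CNO and Gq-Saline libraries together (SD, n = 6 each). Npy, a neuropeptide gene, was higher in olfactory bulb than in cortex (log2 difference 7.05, SE 1.13, adjusted p = 0.000445, 500 ± 233 against 5.92 ± 7.61 normalised reads), and the cadherin gene Cdhr1 had 144.9 ± 46.8 against 0. Car8, a carbonic anhydrase-related gene, was lower in olfactory bulb than in cortex (-4.985, SE 0.354, adjusted p = 1.31e-08, 48.4 ± 32.0 against 1347 ± 451). Chrdl1, an astrocyte-secreted regulator of synapse maturation, was higher in cortex than in hippocampus (2.79, SE 0.192, adjusted p = 1.74e-08, 3124 ± 658 against 450 ± 82.8), and Gfap was lower (-1.84, SE 0.162, adjusted p = 9.19e-07, 1356 ± 422 against 4705 ± 937). Ttr, the choroid plexus carrier of thyroid hormone, was lower in olfactory bulb than in hippocampus (-11.44, SE 1.16, adjusted p = 1.67e-06, 49.1 ± 103.9 against 25460 ± 19760). Npy belongs to the list of olfactory ensheathing markers and Ttr to that of ependymal and choroid markers, so a difference in other cells within the sorts stays open for these genes.

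By group, 9 of 9 olfactory ensheathing markers were higher in olfactory bulb than in hippocampus (median 4.90, adjusted p = 0.00106 with an estimated correlation) and 7 of 9 than in cortex (median 3.33, 0.006201). Of 32 astrocyte transcription factors, 8 were lower and 1 higher in olfactory bulb than in cortex (median -0.43, adjusted p = 0.000664 with an estimated correlation), among them Emx2 and Rorb, and 8 were lower than in hippocampus (median -0.25, 0.000783). The general astrocyte markers moved with them, with 6 of 16 lower and 1 higher than in cortex (median -0.18, adjusted p = 0.197 with an estimated correlation) and 3 lower than in hippocampus (median -0.24, 0.222). GABAergic neuron, fibroblast and endothelial markers had medians of 3.77, 2.00 and 1.64 against cortex, each with an adjusted p = 0.219 with an estimated correlation. limma called 649 genes for olfactory bulb minus cortex (416 higher, 233 lower, edgeR 254 and 278), 472 for olfactory bulb minus hippocampus (289 and 183, edgeR 263 and 250) and 19 for cortex minus hippocampus (11 and 8, edgeR 10 and 10). The count for the last pair was 48 and 51 without cortical saline replicate 1 and 4 and 11 and 12 without cortical Gq-CNO and hippocampal saline replicate 4, and that for olfactory bulb minus hippocampus was 769 without cortical saline replicate 4. Of 100 splits, 1 gave as many genes for each of the 3 pairs of regions, the real one, and the highest others gave 62, 2 and 12, which excludes chance only if libraries of different regions are independent. Xist in Gq-Saline replicate 1 of each region leaves open that libraries of 1 number share a mouse. The splits and the counts here kept no such pairing, and with a replicate block all 3 counts were higher, as given above. Each region is a table of its own, and the labels do not tell whether the libraries of different regions were prepared together. Leading numbers in the column names of replicates 1 and 2 run through cortex, hippocampus and olfactory bulb in turn. What they count is not stated, so region and preparation were not separated.

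Spry2 is a feedback inhibitor that ERK signalling induces, so raised ERK signalling might accompany its rise in olfactory bulb Gq-CNO astrocytes. The other 11 ERK feedback genes had a median log2 change of -0.07078 (95% bootstrap interval -0.40 to 0.20), with 5 higher and 6 lower. They ranged from -0.80 to 1.82 (Phlda1, named after its values were seen, adjusted p = 0.996), so members went both ways, and raised ERK signalling stays open.

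In both sorts, all Gq-CNO libraries had reads of the Y-linked Ddx3y. Gq-Saline replicate 1 of each region and sort and hippocampal astrocyte Gq-Saline replicate 4 had Xist and at most 2 reads of Ddx3y. The split was not clean, since cortical astrocyte Gq-Saline replicate 4 had 77 reads of Xist and 182 of Ddx3y, hippocampal astrocyte Gq-CNO replicate 4 had 15 and 124, and cortical astrocyte Gq-CNO replicate 4 had 1 and 19. The CNO control, flox control and cKO-labelled libraries had Xist and 0 reads of Ddx3y. The untreated libraries had 310, 637 and 19 reads of Xist, and the last of them had 434 of Ddx3y.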
